A study of Mus musculus with 96 samples.

How the data were processed

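Messenger RNA from the cerebellum was sequenced in 96 libraries, each from a tissue specimen of a male or female C57BL/6 mouse that was heterozygous for a knock-in Htt allele or wild type, at 6 or 10 months of age. Knock-in alleles carried CAG repeats of nominally 20, 50, 92 or 140 units, written Q20, Q50, Q92 and Q140. Wild types came from cages shared with Q20 mice or with Q50 mice, per the labels, so each age held 6 groups of 8 libraries, with 4 of each sex. No wild types housed with Q92 or Q140 mice were analysed here. The labels do not say that each library came from a different animal; where 2 libraries shared an animal, the p-values would measure technical spread. Age was confounded with the numbering of the libraries, so no comparison across ages can separate the 2.

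The deposited count table holds expected counts per Ensembl gene, that is, estimated counts that need not be whole; 81.6% of its values were whole at a tolerance of 0. A second table deposited by the authors holds FPKM values of the same genes, fragment counts scaled by gene length and library depth. The submitters' processing notes name CASAVA 1.8.2, an Illumina base calling and demultiplexing package; the aligner, the quantifier, the genome build, the annotation and whether counting used strand are not given in the sources used here. Per the labels' protocols, total RNA was extracted with a Qiagen miRNeasy kit and libraries were made by Illumina protocols. Both tables list 39179 genes, of which 37693 identifiers had a name in the reference annotation used here (GENCODE M21 on GRCm38, the source of all coordinates), 1486 had none and 10464 genes were at 0 in every library. Without a stated strand, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies are called uncertain where they are named. The share of 50-base words of a gene's annotated exons that other annotated genes also hold was computed for 17 genes chosen after their values were seen.

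Library totals ran from 29957797 to 39477325 estimated counts after rounding, with a median of 34251076. Estimated counts were rounded to whole numbers and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with TMM factors and the filterByExpr filter at its defaults, a minimum count of 10 and a minimum total of 15. The fits within an age held its 48 libraries with terms for the 6 groups and for sex, and 41 residual degrees of freedom. The trend over CAG length held the 32 knock-in libraries of an age, with the slope given per 100 CAG. Fits across ages held all 96 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p given for a gene comes from this edgeR test unless another tool is named. Standard errors (SE) of log2 fold changes were computed as the absolute log2 fold change over the square root of F. Log2 CPM values used a prior count of 2. The number of libraries given beside a gene is how many of the 8 case libraries lay on the stated side of the mean of the control libraries.

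The genes named were set by a rule fixed before the data were examined. The rule took Htt everywhere; the 10 called genes highest and the 10 lowest in log2 fold change in Q140 against Q20 at each age, 6 and 6 in Q92 against Q20 and in the trend, and 5 and 5 in the other comparisons, all with a mean log2 CPM of at least 1; the 10 genes called at both ages with the smallest larger adjusted p; up to 4 members of each gene list with the smallest p; and all called genes where a comparison had 5 or fewer. Genes outside it are said to have been chosen after their values were seen.

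Of 35 gene lists fixed before the data were examined, 33 had at least 5 tested members and were tested. They hold markers of Purkinje cells, granule neurons, interneurons, deep nuclei neurons, brainstem neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial cells, meninges, choroid plexus and red blood cells; genes of reactive astrocytes, the interferon response, endoplasmic reticulum stress, heat shock, the proteasome, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, p53 targets, glucocorticoid-induced genes, the circadian clock, immediate early genes, mismatch repair, ion channels, glutamate and GABA receptors, spinocerebellar ataxias, beta-cluster protocadherins, Polycomb-held transcription factors, striatal genes that fall in Huntington disease models and sex-linked genes. Alpha- and gamma-cluster protocadherins (2 tested members) were only counted. Htt itself (1 member) was left out of camera, and its log2 CPM was tested by the permutation below and adjusted together with the lists. Lists were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data; adjusted p-values cover the lists of 1 comparison. A list score is the mean log2 CPM of its members in a library. Score differences between 2 groups of 8 were tested by exact two-sided permutation within sex over 4900 splits, a test added after the data were seen; its smallest possible p is 0.000408.

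Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, limma-trend on log2(FPKM + 1), the replicate number of the labels within sex as a block, surrogate variables from svaseq of sva 3.50.0 (5 to 8 per fit), the L number in the library name as a covariate, all 16 wild types of an age as the control, and leaving out each library in turn. Leaving out the libraries more than 4 median absolute deviations from the median of the first principal component of their age was added after the data were seen; 7 libraries at 6 months and 1 at 10 months met it. The L number takes the values L1 to L8 and, once, L32, and no source used here says what it means. Adjusted p-values that DESeq2 left undefined were kept so. No pair of libraries of 1 group was a duplicate: over 144 pairs, the lowest chi-square per gene was 4.41.

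The fit was tested on simulated data for Q140 against Q20 at 10 months over 17026 genes. It recovered 92 of 100 genes changed 1.5-fold and 76 of 100 changed 1.25-fold, with 7 false calls. Smaller changes were not simulated. Changed genes had a mean log2 CPM of at least 1, and counts were drawn independently, without far-out libraries or differences between cages. The false calls therefore hold only for such data: other splits of the real libraries at 6 months called up to 2515 genes. Some of the genes that the rule for named genes took are not reported here, and they stayed in every fit, count and list test.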

Results

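The series examined how the length of the CAG repeat in Htt, the gene whose repeat expansion causes Huntington disease, relates to gene expression in mouse cerebellum. Messenger RNA was profiled in 96 libraries that formed 24 groups of 4 by genotype, cage, sex and age, or 12 groups of 8 when the sexes were joined. The groups at 6 and at 10 months were heterozygotes with 20, 50, 92 or 140 CAG (Q20, Q50, Q92, Q140), wild types that shared cages with Q20 mice and wild types that shared cages with Q50 mice. Library totals lay between 29957797 and 39477325 estimated counts. Errors of log2 fold changes are standard errors (SE) with 8 libraries per group, and levels in CPM, counts scaled to library size, are given as mean ± SD. The Benjamini-Hochberg adjusted p of a gene in edgeR is written q. Where q is given for 2 groups of 8, all 8 libraries of the first group lay on the stated side of the mean of the other group unless another number is given. Xist, the RNA that silences an X chromosome in female cells, averaged 1341 ± 162 CPM in the 48 female libraries and 0.574 ± 0.530 CPM in the 48 male libraries. The Y-linked gene Ddx3y was at most 0.467 CPM in a female library and at least 32.2 CPM in a male library, so each of the 96 libraries matched its labelled sex.

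Htt (ENSMUSG00000029104, GRCm38 chromosome 5, 34761740 to 34912534) was measured as the sum of both alleles, and the counts do not show the repeat itself. At 10 months it stood at 302 ± 25 CPM in Q20, 291 ± 14.5 in Q50, 279 ± 52.3 in Q92 and 259 ± 13.1 in Q140 (n = 8 each). It stood at 310 ± 8.06 and 294 ± 20.8 CPM in the wild types housed with Q20 and with Q50. The log2 difference between Q140 and Q20 at that age was −0.22 ± 0.07 and did not pass over all genes (edgeR adjusted p = 0.117, lower in 8 of 8 Q140 libraries). An exact two-sided permutation within sex gave p = 0.00204 (adjusted p = 0.0278 over the lists of the comparison). At 6 months the difference was −0.00 ± 0.12 (q = 0.990, 2 of 8 libraries on that side), with library values between 7.15 and 8.30 log2 CPM. Neither knock-in allele differed from its own wild types in Htt, with log2 differences of −0.02 and −0.04 for Q20 and −0.07 and −0.02 for Q50 at 6 and 10 months and adjusted p between 0.926 and 1.

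Q20 and Q50 mice were each compared with wild types from their own cages. In Q20 this asks what a knock-in allele changes apart from a long repeat. In Q50 the allele and its expansion to 50 CAG come together. Abhd1, of the alpha/beta hydrolase family, and Otof, which encodes the synaptic vesicle protein otoferlin, rose in both genotypes at both ages. In Q20, Abhd1 rose by 1.496 ± 0.13 at 6 months (2.82-fold, adjusted p = 2.83e-10, 8 of 8 libraries) and by 1.44 ± 0.12 at 10 months (q = 4.37e-11, 8 of 8). Otof rose by 1.70 ± 0.20 (q = 8.23e-07, 8 of 8) and 1.72 ± 0.19 (q = 7.41e-08, 7 of 8). In Q50, Abhd1 rose by 1.28 ± 0.13 (q = 3.54e-08, 7 of 8) and 1.34 ± 0.12 (q = 3.96e-10, 8 of 8). Otof rose there by 1.69 ± 0.20 (q = 1.13e-06, 8 of 8) and 1.91 ± 0.19 (q = 4.65e-09, 8 of 8). Abhd1 levels at 10 months were 2.55 ± 0.346 CPM in wild types housed with Q20, 6.83 ± 1.71 in Q20, 6.83 ± 0.404 in Q50, 7.07 ± 0.729 in Q92 and 7.12 ± 0.818 in Q140. Both genes lie on the chromosome of Htt, Abhd1 (ENSMUSG00000006638) at 30950066 to 30955091, where it overlaps Preb on the other strand, and Otof (ENSMUSG00000062372) at 30367062 to 30461932 of chromosome 5. None of the 50-base words in their annotated transcripts occurs in another annotated gene.

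**Figure D1:**
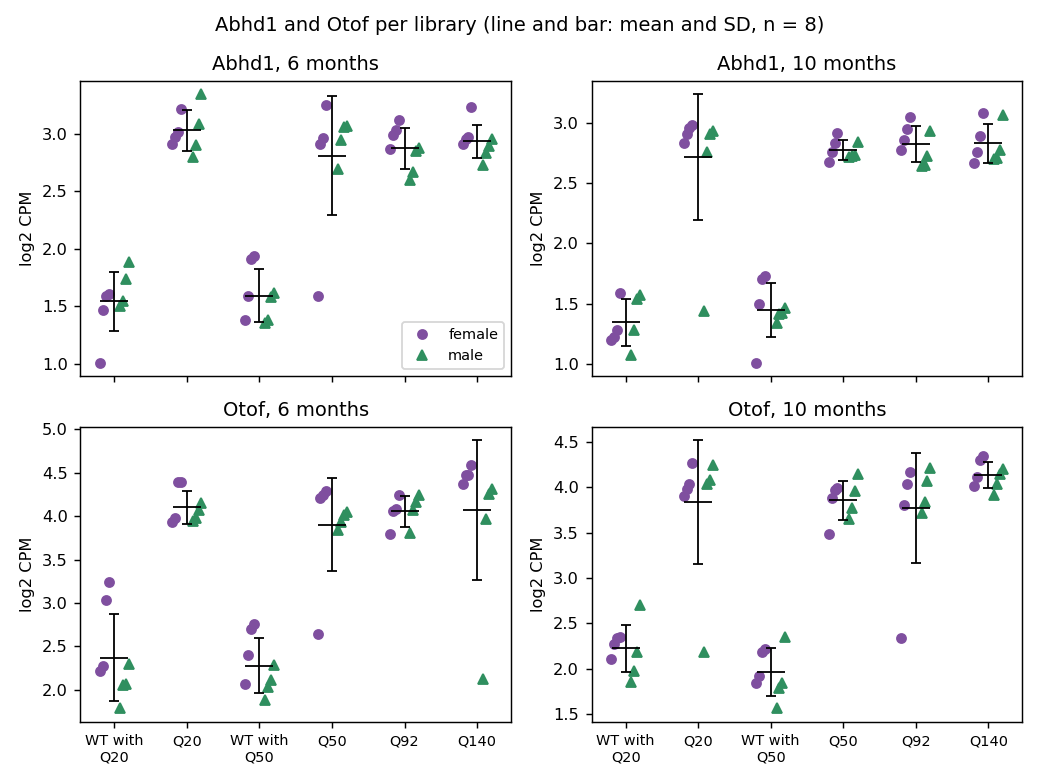
Log2 CPM of Abhd1 and Otof in every library by group, with the mean and SD of each group of 8. The knock-in groups lie above both wild-type groups at both ages, except for single libraries such as Q20 male 3 at 10 months and Q50 female 4 at 6 months, which lie at wild-type levels for both genes.

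Abhd1 and Otof were the only called genes in Q20 at both ages and in Q50 at 6 months (2 of 17120 tested at 6 months and 2 of 17026 at 10 months). Both stayed called under every alternative that gave an adjusted p and every left-out library. In Q50 at 10 months 9 genes passed, 8 higher and 1 lower. Of these 8 (88.9%) lay within 15 Mb of Htt against 1.36% of tested genes (Fisher's exact test, one-sided, adjusted p = 1.99e-13, with a window chosen after the values were seen). Among the 8, Gm5067, Gm10471 and 5031410I06Rik share 51.0%, 48.1% and 97.5% of their 50-base words with other genes, so their counts are uncertain. Atraid, in this window, fell by 0.28 ± 0.05 (q = 0.00502, 8 of 8) and Galnt11 rose by 0.16 ± 0.03 (q = 0.0360), while Igsf11, on chromosome 16, rose by 0.27 ± 0.05 (q = 0.0181). The Galnt11 call ended without any of 10 single libraries, with limma-trend on FPKM and without the low-count filter. The Igsf11 call ended without any of 7, with surrogate variables and, like that of Atraid, with the L number of the library name as a covariate. The count in Q20 at 6 months was 8 without Q20 female 1, 7 without wild type male 1 and 7 without wild type male 3. It was 4 without Q20 female 4, 9 without wild type female 2, 8 without wild type male 2, 11 without the low-count filter and 5 with DESeq2. In Q50 at 6 months it was 4 without Q50 female 4, 4 with DESeq2 and 10 with surrogate variables. In Q20 at 10 months it was 5 without Q20 female 3, 6 with surrogate variables, 5 without the library far out on the first principal component and 1 with DESeq2, which left Abhd1 and Otof without an adjusted p.

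Q140 was compared with Q20, the knock-in control with a short repeat. Each genotype came from cages of its own, and no wild types housed with Q140 were analysed here. At either age a long repeat thus cannot be told apart from differences between cages or cohorts. At 6 months the lower genes included Il20rb, a cytokine receptor subunit (−0.56 ± 0.10, q = 0.00361), and Ccdc63, a coiled-coil protein related to dynein arm docking (−0.56 ± 0.09, q = 0.00291). The potassium channel Kcnk13 (−0.58 ± 0.11, q = 0.00399) and the protease inhibitor Serpinb1a (−0.55 ± 0.11, q = 0.0146) also fell. Genes of oligodendrocytes and myelin fell beside them, among them Car2 (carbonic anhydrase, −0.46 ± 0.09, q = 0.00443) and Aspa (aspartoacylase, −0.46 ± 0.10, q = 0.0205). Mal (−0.46 ± 0.09, q = 0.0126) and the tight junction gene Cldn11 (−0.49 ± 0.11, q = 0.0482) fell too, as did the nuclear RNA Neat1 (−0.44 ± 0.09, q = 0.00698). Higher genes included Tpbg, a Wnt-regulating surface glycoprotein (0.42 ± 0.07, q = 0.00291), and Igsf10 (0.62 ± 0.11, q = 0.00395). The choline transporter-like gene Slc44a5 (0.57 ± 0.11, q = 0.00698) and the protocadherin Pcdhb12 (0.49 ± 0.10, q = 0.0107) rose. So did the potassium channel subunits Dpp10 (0.40 ± 0.08, q = 0.0116) and Kcnab1 (0.23 ± 0.05, q = 0.0146), Ano5 (0.48 ± 0.10, q = 0.0266) and Kctd8 (0.22 ± 0.05, q = 0.0467). Each of these had all 8 Q140 libraries on the stated side of the Q20 mean. Pdlim2 fell by 0.61 ± 0.14 (q = 0.0497, 7 of 8).

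In all, 28 of 17120 genes passed at 6 months, 11 higher and 17 lower, and 3976 had an unadjusted p under 0.05 where 856 were expected by chance. Gm5067 (1.76 ± 0.31, 8 of 8) and Gm10471 (2.11 ± 0.40, 7 of 8), both near Htt and uncertain for the words they share, were among the 11. The count was 17 without Q140 female 3, 62 without Q20 female 1, 55 without Q20 male 3, 834 without Q140 female 4 and 48 without Q20 male 2. It was 173 with DESeq2, 82 with surrogate variables (19 of the 28 among them) and 1131 without the libraries far out on the first principal component. Those include Q140 female 4 and Q20 female 4 and male 4. Leaving out single libraries ended the calls of Kctd8 (13 libraries), Cldn11 and Pdlim2 (10 each), Ano5 (5), Aspa (4), and Mal, Kcnab1 and Serpinb1a (2 each). Against the 16 wild types 38 genes passed, 16 of the 28 among them. Of the 21 genes taken by the rule for named genes, 14 kept their call there. The 7 others were Pcdhb12 (0.16, q = 0.535), Kctd8 (0.14, q = 0.154), Ano5 (0.37, q = 0.0563), Igsf10 (0.35, q = 0.0872), Gm10471 (q = 0.0701), Pdlim2 (−0.40, q = 0.154) and Cldn11 (−0.36, q = 0.105). Surrogate variables ended the calls of Pcdhb12, Ano5, Dpp10, Kcnab1 and Neat1, and the L number those of Ano5, Aspa, Cldn11 and Pdlim2. Cldn11, Pdlim2 and Kctd8 lost theirs without the low-count filter and, with Kcnab1 and Gm10471, with limma-trend on FPKM, and the first 2 also with RLE factors.

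Of 21 tested oligodendrocyte markers, 3 fell at 6 months (17 adjusted over the list alone), with a median of −0.29 and 20 of 21 lower in sign. Camera gave an adjusted p of 3.27e-11 with the preset correlation and adjusted p = 0.557 with an estimated correlation. Among 21 beta-cluster protocadherins, cell adhesion genes of neurons, Pcdhb12 alone rose over all genes (16 adjusted over the list alone), with a median of 0.37 and adjusted p = 0.557 with an estimated correlation. Ion channel genes had a median of 0.19 (2 rose, 6 higher and 1 lower adjusted over the list alone). The medians were 0.18 for glutamate and GABA receptors (0 passed over all genes in edgeR, 9 higher and 2 lower adjusted over the list alone) and 0.13 for Purkinje cell markers (0 passed, 10 higher adjusted over the list alone). Each of the 3 lists had adjusted p = 0.557 with an estimated correlation. Against the 16 wild types oligodendrocyte markers had a median of −0.23, with 3 called lower and 20 of 21 lower in sign. There the medians were 0.15 for beta-cluster protocadherins, whose score was 2.34 in Q20 and 2.55 and 2.60 in the wild types (log2 CPM), 0.09 for ion channels and 0.13 for Purkinje markers. Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, stood apart in the same groups: their score was 0.26 ± 0.87 log2 CPM in Q140 against 2.48 ± 1.69 in Q20 (SD, n = 8). Every group of either age, wild types included, held libraries scoring near 0 and libraries above 2. Wild types housed with Q20 at 6 months, for example, held scores of −0.20 (female 2) and 4.25 (female 1). Group means of this score thus follow which libraries were high, and the cause was not tested. The median log2 difference of these markers in Q140 against Q20 was −2.42, 0 of 17 passed over all genes in edgeR (15 lower adjusted over the list alone) and adjusted p = 0.606 with an estimated correlation.

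RNA measures of whole libraries moved beside these lists at 6 months. The oxidative phosphorylation score was 6.64 ± 0.14 in Q140 against 6.81 ± 0.23 log2 CPM in Q20, and the ribosomal protein score was 6.34 ± 0.19 against 6.56 ± 0.28 (SD, n = 8). Their medians were −0.19 and −0.24, with 0 called in edgeR, 0 adjusted over the list alone and adjusted p = 0.663 each with an estimated correlation. Of the libraries far out on the first principal component, Q20 male 4, Q20 female 4 and Q140 female 4 had 8.27%, 8.13% and 7.92% of counts mitochondrial. Without the far libraries these medians were −0.12 (2 lower called) and −0.15 (5). Oligodendrocyte markers then had a median of −0.21 (9 lower called), beta-cluster protocadherins of 0.31 (10 higher called), ion channels of 0.16 (7 higher) and Purkinje markers of 0.13 (8 higher). Glutamate and GABA receptors had 0.15 (9 higher and 1 lower called) and choroid plexus markers −2.63 (9 lower).

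At 10 months 339 of 17026 genes were called in Q140 against Q20, 180 higher and 159 lower (2350 with an unadjusted p under 0.05, 851 expected by chance). The count exceeded the 28 of 6 months with all libraries, but not without those far out on the first principal component (1131 at 6 and 756 at 10 months). Of the 339 genes, 11 (3.2%) lay within 15 Mb of Htt against 1.36% of tested genes (Fisher's exact test, one-sided, adjusted p = 0.0149). The hypoxia-linked carbonic anhydrase Car9 fell by 0.997 ± 0.145 (q = 4.37e-05), from 8.09 CPM in Q20 to 4.09 in Q140. Ccdc63 (−0.71 ± 0.12, q = 0.000338), Serpinb1a (−0.68 ± 0.13, q = 0.00182) and Tmem52 (−0.70 ± 0.14, q = 0.00224) fell as well. So did Il20rb (−0.64 ± 0.12, q = 0.00150), the metabotropic glutamate receptor Grm4 (−0.41 ± 0.10, q = 0.0178) and the hair-cell myosin Myo15 (−0.84 ± 0.20, q = 0.0153). Rising genes included Igsf10 (0.61 ± 0.10, q = 0.000410), the collagen Col12a1 (0.56 ± 0.09, q = 0.000187) and Syndig1l (0.63 ± 0.11, q = 0.000807). The calcium channel subunit Cacna2d4 (0.58 ± 0.10, q = 0.00107) and the calcium-binding protein gene Necab1 (0.55 ± 0.10, q = 0.00141) rose. Tpbg (0.57 ± 0.11, q = 0.00163), Ppl (0.56 ± 0.11, q = 0.00182) and Slc44a5 (0.53 ± 0.10, q = 0.00208) rose, as did the phospholipase Pla2g4e (0.63 ± 0.13, q = 0.00483) and the G-protein regulator Rgs9 (0.50 ± 0.12, q = 0.0110). All 8 Q140 libraries lay on the stated side for each of these genes.

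Several of the genes called at 10 months came with measured limits. Zbtb16, a transcription factor induced by glucocorticoids, fell by 1.495 ± 0.25 (q = 0.000338, 8 of 8). Its mean log2 CPM was 4.49 in wild types housed with Q20, 4.27 in Q20, 2.57 in wild types housed with Q50, 2.92 in Q50, 3.09 in Q92 and 2.77 in Q140. Msantd1 (−0.65 ± 0.15, q = 0.00931, 8 of 8) overlaps Htt, and Alms1-ps2 (−0.92 ± 0.20, q = 0.00704, 8 of 8) shares 74.1% of its words with other genes. The pituitary hormone Prl (q = 0.0420) was at 2.96 ± 5.23 CPM in Q20 and 0.0921 CPM in Q140, and its call ended without any of 11 single libraries. Vipr2 (−0.64 ± 0.16, q = 0.0191) and Fam205c (0.55 ± 0.14, q = 0.0217) each lost their call without either of 2 libraries. The count was 204 without Q20 male 3, 802 with surrogate variables, 104 with the L number as a covariate, and 756 without Q92 female 2, the library far out on the first principal component. Against all 16 wild types of the age 74 genes passed, 58 of them also called against Q20. Of the 26 genes taken by the rule, 10 kept their call there: Ccdc63 (−0.67, q = 0.000117), Car9 (−0.80, q = 0.000221), Necab1 (0.46, q = 0.00271), Tpbg (0.41, q = 0.0327), Igsf10, Il20rb, Car2, Mirt1, Gm5067 and Gm10471. The 16 others did not. Among higher genes these were Pla2g4e (0.05, q = 0.9998), Fam205c (0.11, q = 0.9998), Col12a1 (0.20, q = 0.553), Syndig1l (0.22, q = 0.682), Slc44a5 (0.31, q = 0.115), Cacna2d4 (0.32, q = 0.114) and Ppl (0.36, q = 0.0655). Among lower genes they were Zbtb16 (−1.10, q = 0.187), Serpinb1a (−0.37, q = 0.181), Tmem52 (−0.36, q = 0.311), Vipr2 (−0.33, q = 0.721), Msantd1 (−0.43, q = 0.181), Myo15 (−0.70, q = 0.0680), Alms1-ps2 (−0.36, q = 0.832), Mal and Prl. With the L number 8 of the 26 calls ended (Pla2g4e, Fam205c, Slc44a5, Vipr2, Msantd1, Myo15, Alms1-ps2 and Mirt1), and the Prl call ended with DESeq2, with limma-trend on FPKM and without the low-count filter.

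**Figure D2:**
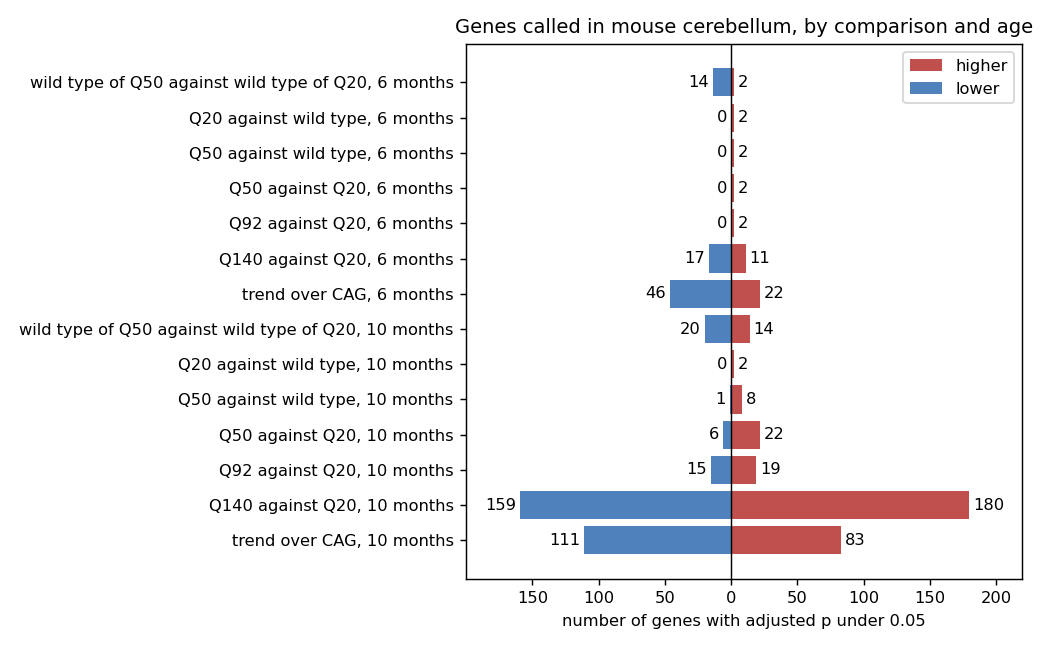
Number of genes called higher (up) and lower (down) in each comparison, at a Benjamini-Hochberg adjusted p under 0.05 in edgeR. Among the comparisons with Q20, Q140 at 10 months has 339 calls, against 34 for Q92 and 28 for Q50 at that age.

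Oligodendrocyte markers were the list with the most called members in Q140 at 10 months. Of 21 tested, 12 fell and none rose (17 lower adjusted over the list alone), with a median of −0.36. Mal fell by 0.53 ± 0.11 (q = 0.00270), Ugt8a, which makes myelin galactolipids, by 0.45 ± 0.09 (q = 0.00364), and the glial connexin Gjc3 by 0.26 ± 0.05 (q = 0.000800). Opalin, another marker, was at 0.09 on the log2 scale. The list score differed by −0.33 between groups (exact two-sided permutation within sex, p = 0.000408, the smallest possible, adjusted p = 0.0139). Camera gave adjusted p = 2.42e-18 with the preset correlation and adjusted p = 0.265 with an estimated correlation. Against the 16 wild types the median was −0.13 and 2 markers fell, and Mal was at −0.27 (q = 0.366). In Q20 itself the markers had a median of 0.23 against wild types of its cages, with all 21 higher in sign, 0 called in edgeR and adjusted p = 0.486 with an estimated correlation.

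**Figure D3:**
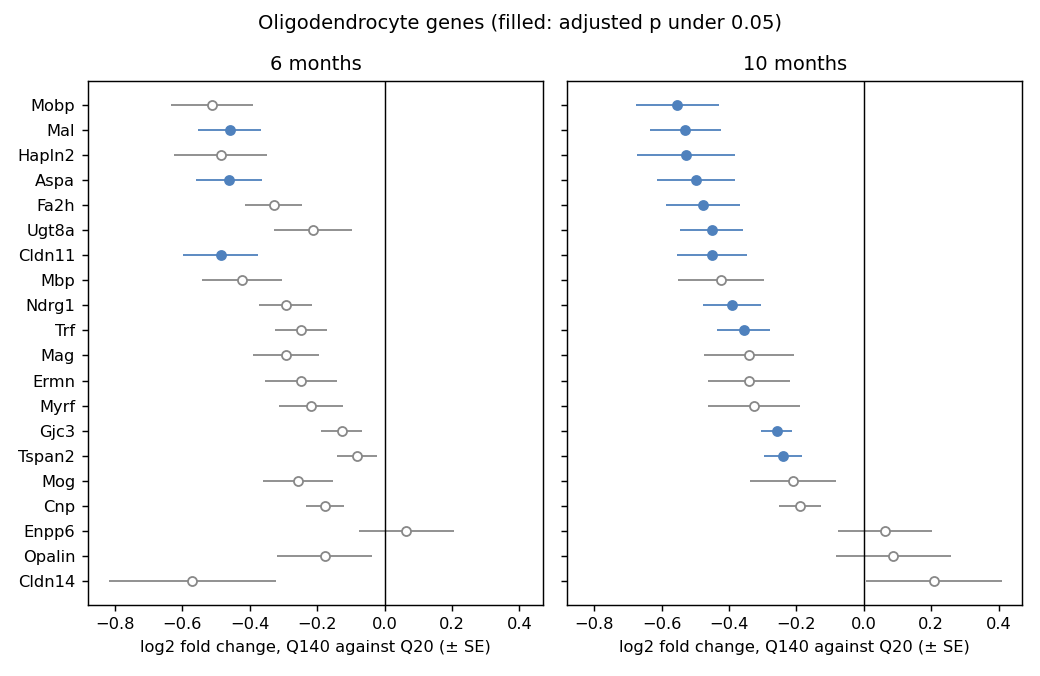
Log2 fold change of the oligodendrocyte markers reported here in Q140 against Q20 at 6 and at 10 months, with bars of 1 SE. At 10 months Mobp is lowest among those drawn, at −0.55.

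Glucocorticoid-induced genes fell in part in the same comparison. Zbtb16 and the metallothioneins Mt1 (−0.42 ± 0.09, q = 0.00450, 8 of 8) and Mt2 (−0.45 ± 0.10, q = 0.00925, 7 of 8) passed, 3 of 18 (6 adjusted over the list alone). The median was −0.29, with all 18 lower in sign, adjusted p = 0.0278 by exact two-sided permutation of the score and adjusted p = 0.265 with an estimated correlation. The list score at 10 months was 4.17 ± 0.13 in Q20 and 4.23 ± 0.24 in wild types of the same cages (log2 CPM, SD, n = 8). It was 3.82 ± 0.22 in Q140, 4.03 ± 0.26 in Q92, 3.84 ± 0.16 in Q50 and 3.77 ± 0.21 in wild types housed with Q50.

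**Figure D4:**
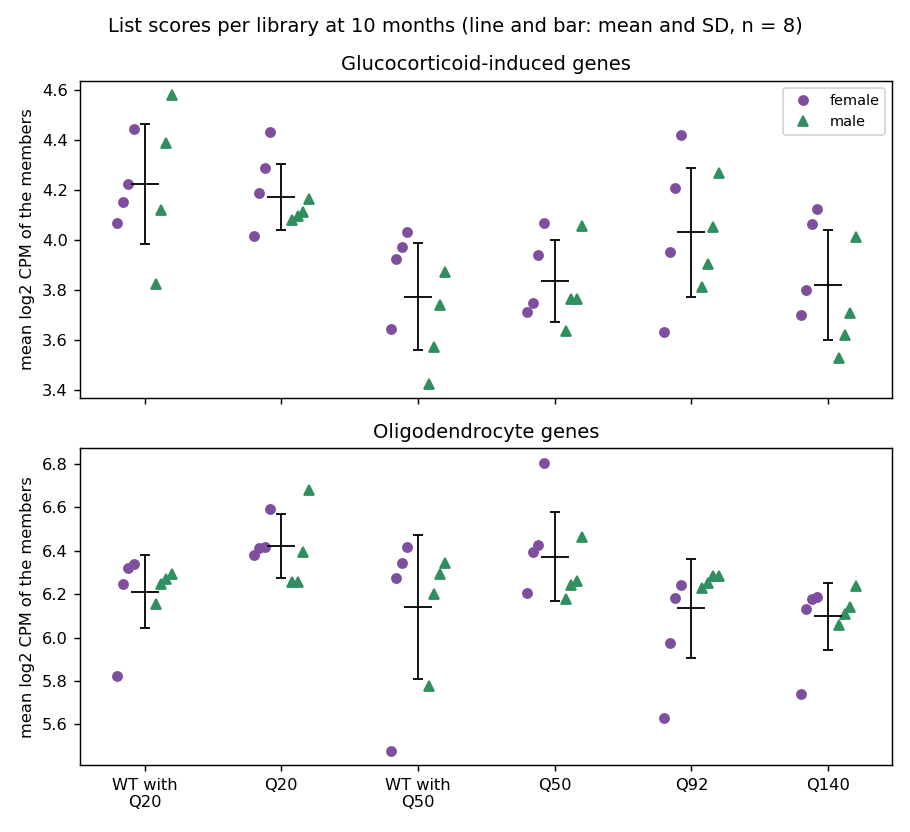
Mean log2 CPM of the glucocorticoid-induced genes and of the oligodendrocyte markers in each library at 10 months, by group, with mean and SD. The glucocorticoid score is 4.17 in Q20 and 3.77 in the wild types housed with Q50.

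The other lists had median log2 differences between −0.29 and 0.33 in Q140 against Q20 at 10 months, with an adjusted p of at least 0.265 with an estimated correlation in each. Neuronal markers had medians of 0.01 (Purkinje cells), −0.04 (granule neurons), 0.03 (interneurons), −0.25 (deep nuclei) and −0.29 (brainstem, where camera pointed up). Glial and vascular markers had medians of −0.05 (astrocytes), −0.09 (reactive astrocytes), −0.10 (oligodendrocyte precursors), 0.05 (microglia), −0.11 (endothelial cells, adjusted p = 0.0347 by exact permutation), 0.06 (meninges), 0.33 (choroid plexus) and −0.17 (red blood cells). Stress and metabolic lists had medians of −0.08 (endoplasmic reticulum stress, where Creld2 fell by 0.23 ± 0.06, q = 0.0297, 7 of 8), −0.08 (heat shock) and −0.03 (proteasome). Further medians were −0.05 (oxidative phosphorylation), −0.05 (ribosomal proteins), 0.02 (cholesterol synthesis), −0.02 (p53 targets), 0.04 (interferon response), 0.05 (circadian clock) and 0.11 (immediate early genes). Medians were 0.05 for mismatch repair genes, of which Pms1 rose by 0.25 ± 0.07 (q = 0.0371, 8 of 8), 0.01 for ion channels, 0.03 for glutamate and GABA receptors and 0.02 for spinocerebellar ataxia genes. They were 0.10 for beta-cluster and 0.03 for the 2 tested alpha- and gamma-cluster protocadherins, 0.02 for Polycomb-held transcription factors, −0.05 for striatal genes that fall in Huntington disease models and 0.06 for sex-linked genes.

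The calls of the 2 ages, which share no library, overlapped. Of 28 genes called in Q140 against Q20 at 6 months, 18 were called in the same direction at 10 months. Among them 7 were higher (Ano5, Dpp10, Gm10471, Gm5067, Igsf10, Slc44a5 and Tpbg) and 11 lower (Aspa, Car2, Ccdc63, Cldn11, Il20rb, Kcnk13, Mal, Mirt1, Mslnl, Prl and Serpinb1a). Chance would give 0.117 and 0.160 among the 16917 genes tested at both (Fisher's exact test, one-sided, p = 4.37e-12 and 4.20e-19). All 28 had the same sign at 10 months, as did 323 of the 339 genes called at 10 months when read at 6 months. The overlap was 68 genes with DESeq2, 48 with surrogate variables, 11 against the 16 wild types and 227 without the libraries far out on the first principal component. Car2, Ccdc63, Il20rb and Tpbg were called at both ages under every alternative and every left-out library. A change between the ages in the difference of Q140 from Q20 was called for 0 of 17449 genes with edgeR (907 with an unadjusted p under 0.05, 2 called with DESeq2). The overlap does not separate repeat length from cages or cohorts either.

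The trend over CAG length was fitted within the 32 knock-in libraries of an age, with the slope per 100 CAG. Each length came from cages of its own, so a slope cannot be told apart from differences between cages or cohorts. Its p-values treat the libraries, not the cages, as replicates. Without any knock-in allele, wild types housed with Q50 and with Q20 differed in 34 genes at 10 months, Zbtb16 among them. Rising or falling with length below describes the fitted slope only. At 6 months Il20rb (−0.44 ± 0.07, q = 0.00532) and the iodide transporter Slc5a5 (−0.51 ± 0.09, q = 0.00964) fell with length. Slc44a5 (0.47 ± 0.08, q = 0.00532), Tpbg (0.35 ± 0.06, q = 0.00633), Igsf10 (0.42 ± 0.08, q = 0.0232) and Necab1 (0.41 ± 0.08, q = 0.0236) rose. At 10 months Serpinb1a (−0.62 ± 0.09, q = 0.000475) and Ugt8a (−0.42 ± 0.06, q = 0.000685) fell with length. So did Mal (−0.47 ± 0.07, q = 0.000962), Ccdc63 (−0.59 ± 0.10, q = 0.00146) and Car9 (−0.78 ± 0.13, q = 0.00201). Tpbg (0.42 ± 0.08, q = 0.00676), Cacna2d4 (0.44 ± 0.09, q = 0.0116), Pde3a (0.42 ± 0.09, q = 0.0116) and the extracellular matrix gene Tnc (0.46 ± 0.11, q = 0.0349) rose. Oligodendrocyte markers had a median slope of −0.31 at 10 months, where 14 of 21 fell (18 adjusted over the list alone) with adjusted p = 0.1 with an estimated correlation. Trpv4 (−1.47 ± 0.35, q = 0.0469) and Igfbp2 (−1.15 ± 0.27, q = 0.0469), both expressed in choroid plexus, fell with length at 6 months. Beside them choroid plexus markers had a median slope of −1.81 (0 called in edgeR, 16 lower adjusted over the list alone) and adjusted p = 0.5 with an estimated correlation. Without the libraries far out on the first principal component it was −1.99 (4 lower called). Each length held libraries scoring near 0 and above 2 for these markers, as given above, and the cause of the slope was not tested.

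In counts, the trend called 68 of 16741 genes at 6 months (22 higher, 46 lower, 4583 with an unadjusted p under 0.05). At 10 months it called 194 of 16747 (83 higher, 111 lower, 1877 with an unadjusted p under 0.05). These counts do not separate length from cages or cohorts either. At 6 months 26 of the 32 libraries moved the count by over 1.5 times when left out, from 8 without Q140 female 3 to 4048 without Q140 female 4. The calls of Trpv4, Igfbp2, Igsf10 and Necab1 ended without 24, 22, 4 and 4 of them. At 10 months the count was 115 without Q140 female 3, 127 without Q140 male 2, 104 without Q140 male 3 and 103 without Q140 male 4. It was 96 without Q20 male 3, 103 without Q20 male 4 and 609 without Q92 female 2, and the Tnc call ended without any of 8 libraries. Counts at the 2 ages were 400 and 326 with DESeq2, 33 and 115 without the low-count filter, and 179 and 658 with surrogate variables. With limma-trend on FPKM the 6-month count was 45. They were 4 and 59 with the L number and 539 and 609 without the libraries far out on the first principal component. The L number ended 11 of the 12 calls taken by the rule at 6 months (Slc5a5, Slc44a5, Tpbg, Necab1, Trpv4 and Igfbp2 among them) and 7 of 12 at 10 months (Tpbg, Cacna2d4, Pde3a and Tnc among them). The Trpv4 and Igfbp2 calls ended with surrogate variables, with limma-trend on FPKM and without the low-count filter too, and the Tnc call with surrogate variables and without that filter.

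Q50 and Q92 were compared with Q20 to ask how shorter expansions differ, with the same limit of cages or cohorts. At 10 months Q50 had lower Zbtb16 (−1.35 ± 0.24, q = 0.00497, 8 of 8) and lower Mertk, a phagocytosis receptor (−0.54 ± 0.11, q = 0.0205). Prr5 (−0.49 ± 0.11, q = 0.0424), Mt2 (−0.45 ± 0.10, q = 0.0424) and the inositol kinase Itpk1 (−0.25 ± 0.05, q = 0.0125) were lower too. Mdga1 (0.59 ± 0.11, q = 0.00850), Zfhx4 (0.68 ± 0.14, q = 0.0209) and the aldehyde oxidase Aox1 (0.48 ± 0.10, q = 0.0238) rose. So did Slc35f4 (0.74 ± 0.17, q = 0.0478) and the brain collagen Col25a1 (1.63 ± 0.33, q = 0.0175, 7 of 8). Glucocorticoid-induced genes had a median of −0.24 there, with 2 of 18 lower (9 adjusted over the list alone), adjusted p = 0.0555 by exact permutation of the score and adjusted p = 0.408 with an estimated correlation. Against the 16 wild types the median was −0.14 and 0 were called in edgeR. Brainstem markers moved beside them, with a median of 1.51, 0 called in edgeR, 6 of 10 higher adjusted over the list alone and adjusted p = 0.597 with an estimated correlation. Choroid plexus markers had a median of 1.14 against Q20 and 0.91 against the 16 wild types. Purkinje markers had −0.11 and −0.20, and 0 of either list were called against the wild types. In all, 28 genes passed (22 higher, 6 lower, 2073 with an unadjusted p under 0.05), 5 of them within 15 Mb of Htt.

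The Q50 count at 10 months was 102 with DESeq2, 8 with limma-trend on FPKM, 7 with surrogate variables, 6 with the L number, 12 against the 16 wild types (5 of the 28 among them), and 174 without the library far out on the first principal component. It was 18 without Q20 female 1, 10 without Q20 male 3, 102 without Q50 female 1, 48 without Q50 male 3 and 13 without Q20 female 2. It was 100 without Q20 female 4, 17 without Q20 male 2, 8 without Q50 female 2, 74 without Q50 female 4 and 11 without Q50 male 2. Calls ended for Mt2, Prr5 and Slc35f4 without any of 10 libraries each, for Aox1 and Zfhx4 without any of 5 and for Mertk and Col25a1 without either of 2. All 10 genes named for Q50 lost their call against the 16 wild types, where Zbtb16 was at −0.96 (q = 0.250), Col25a1 at 0.98 (q = 0.166), Mdga1 at 0.33 (q = 0.182) and Zfhx4 at 0.21 (q = 0.622). Surrogate variables ended 9 of the 10 calls (all but Zbtb16), the L number 8 (all but Zbtb16 and Itpk1) and limma-trend on FPKM 7 (all but Zbtb16, Itpk1 and Mertk). At 6 months only Gm5067 (1.82 ± 0.31, 7 of 8) and Gm10471 (2.87 ± 0.38, 8 of 8), whose counts are uncertain for the copies named above, passed in Q50 (1406 genes with an unadjusted p under 0.05). The count was 6 without Q50 male 3, 7 with DESeq2, 6 with surrogate variables and 5 against the 16 wild types, and the Gm5067 call ended without the far libraries.

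In Q92 at 10 months Zbtb16 (−1.07 ± 0.24, q = 0.0406), the integrin Itgb7 (−0.43 ± 0.09, q = 0.0251) and the hyaluronan-degrading Cemip (−0.41 ± 0.09, q = 0.0429) fell. So did the transferrin gene Trf, made by oligodendrocytes (−0.36 ± 0.08, q = 0.0306). Frem1 (0.45 ± 0.09, q = 0.0179), the organic anion transporter Slco1a4 (0.41 ± 0.08, q = 0.0209) and the active zone gene Erc2 (0.25 ± 0.05, q = 0.0288) rose. So did Adgrl3 (0.26 ± 0.06, q = 0.0363), Pipox (0.48 ± 0.11, q = 0.0406) and Lgr6 (0.45 ± 0.11, q = 0.0499). Oligodendrocyte markers had a median of −0.30, with all 21 lower in sign, 1 called (14 adjusted over the list alone) and adjusted p = 0.604 with an estimated correlation. Against the 16 wild types their median was −0.04 and 0 were called in edgeR. Interferon-response genes (median 0.49, 14 higher adjusted over the list alone, adjusted p = 0.604 with an estimated correlation), meninges markers (0.55, 7 higher, adjusted p = 0.626) and Purkinje markers (0.18, 9 higher, adjusted p = 0.604) had 0 members called over all genes in edgeR. The group held Q92 female 2, far out on the first principal component, with 12.65% of its counts mitochondrial and 1.02% ribosomal RNA. Without it the medians were 0.26 for interferon-response genes, 0.18 for meninges and 0.15 for Purkinje markers, with 0 members of each higher adjusted over the list alone. Purkinje markers had a median of 0.08 against the 16 wild types. In all, 34 genes passed (19 higher, 15 lower, 2735 with an unadjusted p under 0.05). Of the 34, 4 (11.8%) lay within 15 Mb of Htt against 1.36% of tested genes (Fisher's exact test, one-sided, adjusted p = 0.00252).

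The Q92 count at 10 months was 6 without Q20 male 3, 94 without Q92 female 1, 52 without Q92 male 3, 16 without Q20 male 4 and 15 without Q92 female 4. It was 218 with DESeq2, 14 without the low-count filter, 6 with limma-trend on FPKM, 1 with the L number and 9 against the 16 wild types (4 of the 34 among them). All 12 genes taken by the rule lost their call against the 16 wild types, where Zbtb16 was at −0.68 (q = 0.420), Cemip at −0.39 (q = 0.172), Slco1a4 at 0.28 (q = 0.374), Frem1 at 0.15 (q = 0.436) and Trf at −0.10 (q = 0.518). All 12 lost it with the L number as well, 8 with limma-trend on FPKM and 6 with surrogate variables. Without Q92 female 2 it was 33, of which 22 were among the 34, and Zbtb16, Cemip, Lgr6, Pipox and Adgrl3 were not called. Single left-out libraries ended the calls of Zbtb16 (11 libraries), Cemip and Lgr6 (10 each), Pipox (8), Trf and Adgrl3 (4 each) and Erc2 and Itgb7 (3 each). At 6 months Gm5067 (1.93 ± 0.31, 8 of 8) and Gm10471 (2.50 ± 0.39, 7 of 8) were again the 2 called genes (4224 with an unadjusted p under 0.05). There were 4 without Q20 male 3, 1 with DESeq2, 32 with surrogate variables and 6 against the 16 wild types. The beta-cluster protocadherin score was higher by 0.39 (exact two-sided permutation, adjusted p = 0.0416; 14 members higher adjusted over the list alone, 0 called over all genes in edgeR), with adjusted p = 0.628 with an estimated correlation. Their median was 0.31 against Q20, 0.14 against the 16 wild types and 0.26 against Q20 without the libraries far out on the first principal component. Beside it, oxidative phosphorylation and ribosomal protein genes had medians of −0.22 and −0.26, which were −0.09 each without those libraries. Choroid plexus markers had medians of −0.98 against Q20 and −1.05 against the 16 wild types. Against the wild types all 17 were lower in sign and 0 were called.

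**Figure D5:**
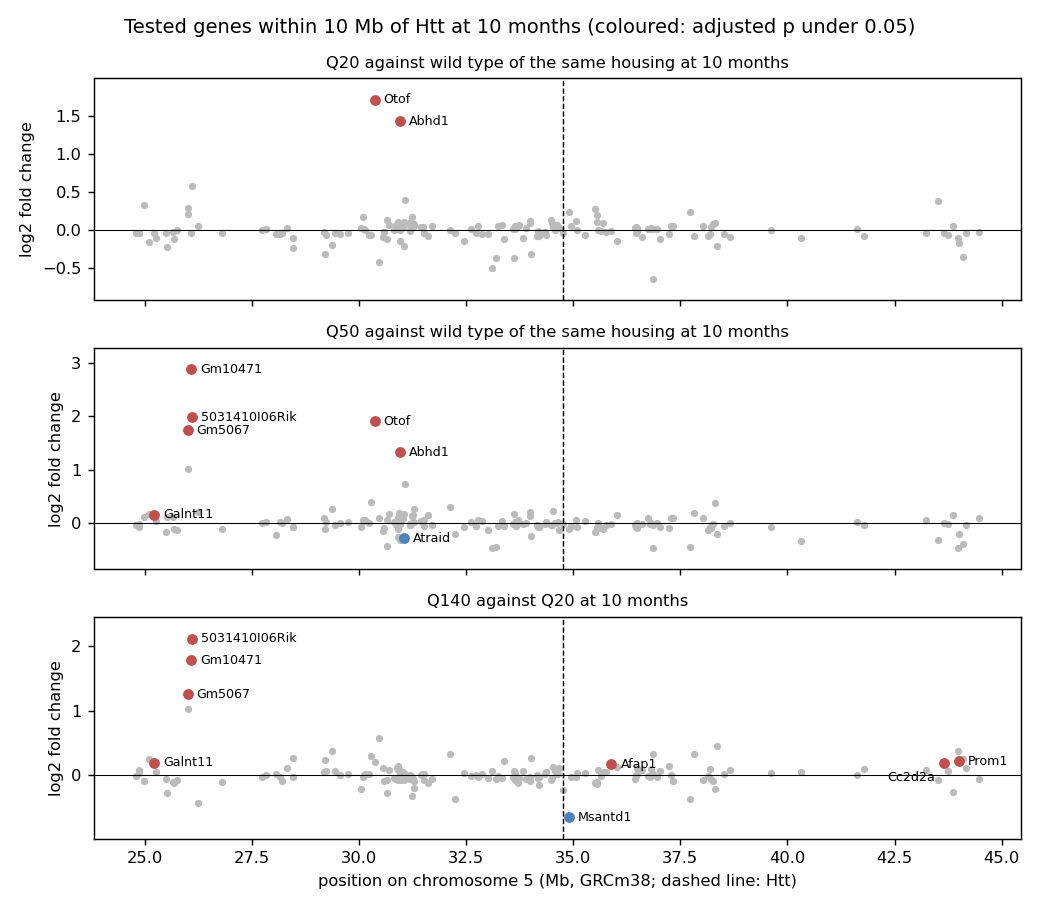
Log2 fold change of tested genes within 10 Mb of Htt on chromosome 5, by position on GRCm38, in 3 comparisons at 10 months. In Q20 against its wild types Abhd1 and Otof stand above their neighbours at 1.44 and 1.72, while Gm10471, whose count is uncertain, is highest in Q50 against its wild types at 2.88.

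The 2 wild-type groups carried no knock-in allele and were compared to ask what differs between cages. At 10 months wild types housed with Q50 had lower Zbtb16 (−1.94 ± 0.25, q = 1.05e-05) and Hif3a, a hypoxia-inducible factor (−1.28 ± 0.22, q = 0.00297). The cell-cycle inhibitor Cdkn1a (−0.80 ± 0.14, q = 0.00297), Mertk (−0.62 ± 0.11, q = 0.00367) and Prr5 (−0.56 ± 0.11, q = 0.00731) were lower as well. Each was lower in 8 of 8 libraries, and Mt2 in 7 of 8 (−0.46 ± 0.10, q = 0.0258). The Notch ligand Dll4 (0.65 ± 0.13, q = 0.00757), Slc22a21 (0.53 ± 0.10, q = 0.00682) and Filip1 (0.39 ± 0.08, q = 0.0197) rose. So did the death ligand Tnfsf10 (0.62 ± 0.14, q = 0.0329), the pericyte gene Pdgfrb (0.22 ± 0.05, q = 0.0365) and Nnt (0.42 ± 0.10, q = 0.0406, 7 of 8). Of 18 glucocorticoid-induced genes 3 fell (10 adjusted over the list alone), with a median of −0.34, adjusted p = 0.0347 by exact permutation of the score and adjusted p = 0.0825 with an estimated correlation. Meninges markers had a median of 0.58, 0 called over all genes in edgeR, 11 of 17 higher adjusted over the list alone, adjusted p = 0.0393 by exact permutation and adjusted p = 0.322 with an estimated correlation. In all, 34 genes passed (14 higher, 20 lower, 1838 with an unadjusted p under 0.05), and 0 of the 34 lay within 15 Mb of Htt.

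The count between wild types at 10 months was 20 without Q20-housed female 3, 21 without Q50-housed female 3, 59 without Q50-housed male 1, 22 without Q50-housed male 3, 18 without Q50-housed female 4, 22 without Q20-housed male 4 and 74 without Q50-housed male 2. It was 108 with DESeq2, 196 with surrogate variables, 5 with the L number and 224 without the library far out on the first principal component. Calls of Nnt, Tnfsf10 and Filip1 ended without any of 10, 9 and 5 libraries. The L number ended 7 of 10 calls taken by the rule (Cdkn1a, Mertk, Prr5, Slc22a21, Tnfsf10, Filip1 and Nnt), and limma-trend on FPKM and the missing low-count filter those of Filip1 and Nnt. At 6 months 16 genes passed, 2 higher and 14 lower (1366 with an unadjusted p under 0.05). Tac1, the substance P precursor, was lower in wild types housed with Q50 (−2.77 ± 0.52, q = 0.0158). The noradrenaline transporter Slc6a2 averaged 0.0725 CPM there against 1.90 ± 2.36 CPM, and Baiap3 averaged 1.82 ± 0.347 against 5.98 ± 6.79 CPM. Basp1 (−0.98 ± 0.22) and Rn7sk (−3.12 ± 0.69, q = 0.0438 each) were also lower. Tmem181a (0.64 ± 0.12) was higher, with 29.0% of its words in copies. Brainstem and deep nuclei markers were lower in the same libraries, with medians of −2.11 and −0.31, adjusted p = 0.00694 each by exact permutation. Over the list alone 6 of 8 and 7 of 12 were lower, and each list had adjusted p = 0.0924 with an estimated correlation. Slc6a2 stood at 1.86, 1.79 and 2.69 log2 CPM in Q20-housed female 1, female 2 and male 1. In the other Q20-housed libraries it lay between −3.16 and −0.52. Tac1 was at 2.55 in Q20-housed female 1 and between −2.09 and 0.98 in the others. These differences thus follow which Q20-housed libraries were high. Both lists were fixed to watch for other tissue in the dissection, and the cause was not tested. Microglia markers had a median of −0.18 (9 lower adjusted over the list alone, adjusted p = 0.0924 with an estimated correlation). The 6-month count was 0 without Q20-housed female 1, 27 without Q20-housed female 3, 37 without Q20-housed male 3, 27 without Q20-housed female 2, 32 without Q20-housed male 2 and 10 without Q20-housed male 4. It was 30 with DESeq2 and 31 without the low-count filter. No gene passed with limma-trend on FPKM, surrogate variables, the L number or without the libraries far out on the first principal component. Single libraries ended the calls of Basp1 (10), Rn7sk (9), Baiap3 (2) and Tmem181a (1).

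Wild types at 10 months were compared with those at 6 months as the course of age without the allele, though the ages also differ in library numbering. Ostn, a muscle and brain secreted peptide gene, rose by 1.05 ± 0.12 (q = 1.25e-09), Zbtb37 by 0.67 ± 0.14 (q = 0.00191) and Syne1 by 0.61 ± 0.13 (q = 0.00205). The BK potassium channel Kcnma1 rose by 0.61 ± 0.19 (q = 0.0264) and complement C4b by 0.37 ± 0.09 (q = 0.00408). The transcription factor Foxp2 rose by 0.31 ± 0.07 (q = 0.00205) and the microglial receptor Cx3cr1 by 0.25 ± 0.06 (q = 0.00316). Opalin fell by 0.39 ± 0.11 (q = 0.0205) and the clock output gene Dbp by 0.39 ± 0.08 (q = 0.00158). Cldn11 fell by 0.37 ± 0.08 (q = 0.00207), the ribosomal gene Rpl27 by 0.42 ± 0.08 (q = 0.000782) and the respiratory chain gene Atp5k by 0.30 ± 0.08 (q = 0.0131). All 16 wild types of 10 months lay on the stated side of the 6-month mean for these genes, except for 14 for Opalin and 13 for Dbp. By list, 11 Purkinje markers (13 adjusted over the list alone), 10 glutamate and GABA receptors (11), 7 beta-cluster protocadherins (13), 6 ion channels (9) and 5 microglia markers (7) rose. In turn 12 oxidative phosphorylation genes (30 adjusted over the list alone), 8 proteasome genes (17), 6 ribosomal protein genes (12) and 5 oligodendrocyte markers (9) fell. For each of these lists the adjusted p with an estimated correlation was between 0.62 and 0.64. The 6-month wild types included 2 libraries far out on the first principal component, Q20-housed male 4 and Q50-housed female 1, with 8.41% and 8.31% of counts mitochondrial. Without the far libraries the medians moved from −0.15 to −0.06 for oxidative phosphorylation (8 lower called), from −0.10 to −0.05 for proteasome (4), from −0.15 to −0.04 for ribosomal protein genes (4) and from −0.16 to −0.13 for oligodendrocyte markers (2). They moved from 0.13 to 0.14 for Purkinje markers (12 higher called), from 0.09 to 0.06 for receptors (10), from 0.21 to 0.16 for beta-cluster protocadherins (6), from 0.11 to 0.06 for ion channels (6) and from 0.11 to 0.16 for microglia markers (9). In all, 1992 of 17449 genes passed, 883 higher and 1109 lower (5264 with an unadjusted p under 0.05). The count was 716 without Q50-housed 6-month female 1, 1136 without Q50-housed 6-month male 3, 692 without Q20-housed 6-month male 4 and 457 with surrogate variables, where the Syne1 call ended.

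The difference of Q140 from Q20 was compared between the sexes, since each group held 4 females and 4 males. Ciart, a repressor of the circadian clock, was the only gene called at 10 months (log2 difference of effects, male minus female, −0.93 ± 0.16, q = 0.0119). There 1062 of 17378 genes had an unadjusted p under 0.05. The count was 3 with DESeq2, 3 with surrogate variables, 2 with the L number and 4 without the library far out on the first principal component. Ciart was not called without Q140 male 3, Q20 female 3, Q20 female 4 or Q20 male 4, with the adjusted p reaching 0.0899. Clock genes as a list had a median difference of −0.35 (1 lower over all genes, 1 higher and 11 lower adjusted over the list alone). The list was the only one of all comparisons to pass with an estimated correlation (adjusted p = 0.0179). That adjustment covers the lists of 1 comparison, so 1 pass among 627 list tests may be chance. At 6 months 0 of 17477 genes passed with edgeR (587 with an unadjusted p under 0.05, 3 called with DESeq2).

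Male and female wild types were compared over both ages. Of 17796 genes 38 passed, 10 higher and 28 lower in males (1399 with an unadjusted p under 0.05). The X-linked genes Eif2s3x (−0.61 ± 0.03, q = 8.25e-34) and Kdm6a (−0.55 ± 0.06, q = 1.41e-09), which escape X inactivation, were lower in males. So were the prolactin family gene Prl2c3 (−0.99 ± 0.13, q = 1.01e-07), the monooxygenase Fmo2 (−0.72 ± 0.13, q = 0.000484) and the clock genes Dbp (−0.42 ± 0.07, q = 1.86e-05) and Ciart (−0.40 ± 0.06, q = 2.57e-05). Ldoc1 was higher in males (0.43 ± 0.08, q = 0.00113). All 16 male wild types lay on the stated side of the female mean for these genes, except for 15 for Fmo2, Dbp and Ciart. The count was 300 with surrogate variables and 223 without the libraries far out on the first principal component.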

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

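The tests of single libraries against their group for Abhd1, Otof and Zbtb16 and for the scores of 3 gene lists were tests chosen after the results were seen, while Htt and the test between the sexes were fixed before.

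For Htt, these 3 genes, these 3 scores and the library total, 96 groups of 8 values were examined, and 15 held a library whose gap to its nearest neighbour exceeded the critical share of the range, where chance marks about 1 in 20 groups. For Htt the libraries below their group were wild type housed with Q20 male 4 at 6 months (7.155 log2 CPM, others from 7.99 to 8.28), Q20 male 4 at 6 months (7.247), Q140 female 4 at 6 months (7.481) and Q92 female 2 at 10 months (7.276). These 4 are among the libraries far out on the first principal component, and without that set the count in Q140 against Q20 at 6 months was 1131 in place of 28. For Abhd1 they were wild type housed with Q20 female 1 at 6 months (1.006), Q50 female 4 at 6 months (1.589) and Q20 male 3 at 10 months (1.435). For Otof they were Q50 female 4 at 6 months (2.645), Q140 male 4 at 6 months (2.125), Q20 male 3 at 10 months (2.179) and Q92 female 2 at 10 months (2.337). The oligodendrocyte score was low in wild type housed with Q20 female 2 (5.822) and Q140 female 1 (5.74) and high in Q50 female 2 (6.806), all at 10 months. The choroid plexus score was high in Q140 male 3 at 6 months (2.361), with the other 7 libraries of its group between −0.28 and 0.32.

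The difference of Q140 from Q20 in Ciart was not the same in males and females at 10 months (−0.9338 on the log2 scale, edgeR q = 0.0119). Nor was that in the clock genes as a list (adjusted p = 0.01787 with an estimated correlation). Of 45 splits 5 gave at least 1 called gene, the real one included, with a highest other of 10, so chance cannot be excluded for the count of 1. Nor can it for the list, since 1 of 627 list tests passed and the adjustment covers 1 comparison.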

How the results depend on the processing

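Leaving out the libraries far out on the first principal component, the exact permutation of list scores and 2 of the overlap alternatives were tests chosen after the results were seen, and all other alternatives were fixed before. With RLE factors no count moved by over 1.5 times. The cause of the changes below was not tested.

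With DESeq2 the counts of called genes at 6 months were 7 in Q50, 1 in Q92 and 173 in Q140 against Q20, 5 in Q20 and 4 in Q50 against own wild types and 30 between wild types. At 10 months they were 102 in Q50 and 218 in Q92 against Q20, 1 in Q20 against own wild types and 108 between wild types. DESeq2 gave 400 and 326 for the trend at 6 and 10 months, 2 for the difference between ages, 3 and 3 for the difference between sexes at 6 and 10 months, and 68 for the overlap of ages. For Abhd1 and Otof in Q20 at 10 months it left the adjusted p undefined, as for 15514 genes there. Without the low-count filter counts were 11 in Q20 against wild types and 31 between wild types at 6 months, 14 in Q92 against Q20 at 10 months, and 33 and 115 for the trend. With limma-trend on FPKM they were 0 between wild types and 45 for the trend at 6 months (edgeR 16 and 68), and 8 in Q50 and 6 in Q92 against Q20 at 10 months.

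With surrogate variables counts at 6 months were 6 in Q50, 32 in Q92 and 82 in Q140 against Q20, 10 in Q50 against wild types and 0 between wild types, where edgeR without them had 16 (1366 with an unadjusted p under 0.05). At 10 months they were 7 in Q50 and 802 in Q140 against Q20, 6 in Q20 against wild types, 196 between wild types and 3 for the difference between sexes. The trend gave 179 and 658, wild types of 10 against 6 months 457, males against females 300 and the overlap 48. With the L number counts were 0 between wild types and 4 for the trend at 6 months. At 10 months they were 6 in Q50, 1 in Q92 and 104 in Q140 against Q20, 5 between wild types, 59 for the trend and 2 for the difference between sexes. Against all 16 wild types counts were 5 in Q50 and 6 in Q92 at 6 months, and 12 in Q50, 9 in Q92 and 74 in Q140 at 10 months, with an overlap of 11.

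Without the libraries far out on the first principal component, 7 at 6 months and 1 at 10 months, counts were 1131 in Q140 against Q20 and 0 between wild types at 6 months. At 10 months they were 174 in Q50 and 756 in Q140 against Q20, 5 in Q20 against wild types, 224 between wild types and 4 for the difference between sexes. The trend gave 539 and 609, males against females 223 and the overlap 227. At 10 months the 1 library left out, Q92 female 2, is in neither group of most of these comparisons and only shares their fit.

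The replicate number as a block moved the count to 6 between wild types at 6 months, and at 10 months to 72 in Q92 against Q20, 61 between wild types and 2 for the difference between sexes, and it moved no other count by over 1.5 times. Of 144 results for named genes 129 kept their call with it. The numbers did not pair the samples: same-numbered libraries had a median correlation of deviations of 0.011 at 6 months and 0.032 at 10 months, with 40 and 38 of 120 pairs over 0.1.

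Of 627 list tests 228 passed with the preset correlation, 227 with RLE factors and 1 with an estimated correlation. By exact permutation of scores 13 of 396 passed, where the preset correlation passed 154 of the same tests.

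Leaving out 1 library at a time gave counts at 6 months of 2 to 6 in Q50, 2 to 4 in Q92 and 17 (without Q140 female 3) to 834 (without Q140 female 4) in Q140 against Q20, 2 to 9 in Q20 and 2 to 4 in Q50 against own wild types and 0 (without Q20-housed female 1) to 37 (without Q20-housed male 3) between wild types. At 10 months the ranges were 8 (without Q50 female 2) to 102 (without Q50 female 1) in Q50, 6 (without Q20 male 3) to 94 (without Q92 female 1) in Q92, 204 (without Q20 male 3) to 358 in Q140, 2 to 5 in Q20 and 7 to 10 in Q50 against own wild types and 18 to 74 between wild types. The trend ranged from 8 (without Q140 female 3) to 4048 (without Q140 female 4) at 6 months and from 96 (without Q20 male 3) to 609 (without Q92 female 2) at 10 months, wild types of 10 against 6 months from 692 to 2932, males against females from 31 to 50, the difference between sexes at 10 months from 0 to 1, and the differences between ages and between sexes at 6 months from 0 to 0.

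Of 144 results for named genes, 89 stayed called in every leave-out, 55 lost the call in at least 1 and 0 changed sign. The call was kept in 135 of 136 with DESeq2, 141 of 144 with RLE factors, 120 without the filter, 105 with limma-trend, 104 with surrogate variables, 70 of 134 with the L number, 28 of 73 against all wild types and 131 without the far libraries. The direction turned only with surrogate variables in wild types of 10 against 6 months, to 0.39 for Gm7336, 0.69 for Gm26723 and 0.44 for ENSMUSG00000073231. Depth limits genes of low counts such as Gm10471, whose group means lay between 0.122 and 0.596 CPM, and Slc6a2, between 0.0725 and 1.90 CPM.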

Other observations

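All 7 tests of explanations in this part were chosen after the results were seen, and the test of the oligodendrocyte share replaced an earlier version whose result was known, while the splits of the samples were fixed before.

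Wild types housed with Q50 differed from those housed with Q20 at 10 months in further gene groups. Cholesterol synthesis genes had a median of 0.14 (22 of 23 higher in sign, 0 called over all genes in edgeR, 5 higher adjusted over the list alone), with adjusted p = 0.0389 by exact two-sided permutation of the score and adjusted p = 0.216 with an estimated correlation. Brainstem markers had a median of 0.79 (9 of 10 higher in sign, 0 called, adjusted p = 0.0347 by exact permutation, adjusted p = 0.525 with an estimated correlation) and endothelial markers of 0.12 (1 of 18 called higher, adjusted p = 0.0347 by exact permutation, adjusted p = 0.525 with an estimated correlation). In Q50 against Q20 at that age the cholesterol genes had a median of 0.15 (12 of 23 higher adjusted over the list alone, 0 called over all genes, adjusted p = 0.513 with an estimated correlation). The difference of Q140 from Q20 in choroid plexus markers changed between 6 and 10 months by a median of 2.76. Over the list alone 16 of 17 were higher, with 0 called over all genes in edgeR and adjusted p = 0.634 with an estimated correlation. Scores within Q140 at 10 months ran from 0.10 (female 4) to 4.02 (male 4), so this change is not read as an effect of Q140.

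Abhd1 and Otof differed between knock-in and wild-type mice, with slopes per 100 CAG within the knock-in libraries of −0.06 ± 0.10 and 0.10 ± 0.15 at 6 months and 0.06 ± 0.09 and 0.16 ± 0.15 at 10 months (adjusted p between 0.686 and 0.883). The tables argue against longer repeats acting on these 2 genes, since the highest upper 95% bound of their change from Q20 to Q140 was 0.5562, under 0.5 of their rise from wild type to Q20, which is 0.718 to 0.857. For the other 5 genes near Htt that were higher in Q50, a part of length cannot be told apart: Galnt11, Gm5067 and 5031410I06Rik were called against Q20 in each of Q50, Q92 and Q140 at 10 months, as were Gm5067 and Gm10471 at 6 months, while the lowest adjusted p of the 5 trends at 10 months was 0.08513 and only 6030443J06Rik had an upper bound (0.46) under 0.5 of its Q50 rise. A candidate explanation is DNA of another origin carried along with the knock-in allele: 88.89% of the genes called in Q50 against wild type at 10 months lay within 15 Mb of Htt, against 0 of 16 and 0 of 34 among wild types at 6 and 10 months, though 3 of those 8 genes (Gm5067, Gm10471 and 5031410I06Rik) share 51.0%, 48.1% and 97.5% of their words with other genes and are uncertain. Single knock-in libraries at wild-type levels of Abhd1 and Otof, such as Q20 male 3 at 10 months, may have lost it by recombination or carry a wrong label, which was not tested.

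The lower oligodendrocyte genes in Q140 at 10 months were set against 2 other accounts. One is a smaller share of oligodendrocytes, which was taken to move members in proportion to their gains. A gain is how a member follows the list score in the other 4 groups. The 19 members, with gains of 0.23 to 1.35, differed from that (exact two-sided permutation within sex, p = 0.0004082, the smallest possible). The p was the same without Opalin and in a first version that asked for equal shifts. Gains come from variation between libraries, which was not shown to follow cell share, so the test cannot exclude a smaller share. The spread around the expected differences was 0.176 (SD), of which errors of the gains give 0.0281, with a correlation of gain and difference of −0.25 across genes, which are not independent replicates. Whether Q20 mice were raised instead cannot be told apart at 10 months, since the median against the 16 wild types was −0.1336 with 2 members called lower, between what either account needs. At 6 months, an age for which no bound was set, that median was −0.23 with 3 members called lower and 20 of 21 lower in sign, which goes against raised markers in Q20 as the whole cause there.

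For the lower glucocorticoid-induced genes in Q50 against Q20 at 10 months, the tables argue against CAG length: Q50 minus its own wild types was 0.06 ± 0.09, with a lower 95% bound of −0.1307, above −0.168, which is 0.5 of the Q50 minus Q20 difference. A difference between cages or cohorts may account for it, since wild types housed with Q50 and with Q20 differed the same way without any knock-in allele (exact two-sided permutation, p = 0.001224). For Q140 the same genes stay open, since wild types of its own cages were not analysed here.

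Other splits of the same libraries were refitted, 45 for comparisons within an age, 60 for the trend and 21 for fits over all libraries, the real one included. Only the real split reached the count for Q50 (2 real, 1 highest other) and Q92 (2, 1) against Q20 at 6 months. The same held for Q50 (28, 3), Q92 (34, 1) and Q140 (339, 1) against Q20 at 10 months. It held for Q20 against own wild types at 10 months (2, 1) and for wild types against wild types at 6 (16, 3) and 10 months (34, 0). It held too for the trend at 6 (68, 1) and 10 months (194, 97). Wild types of 10 against 6 months (1992, 73) were alike in this. For males against females (38, 0) the outcome was fixed in advance. The calls include sex-linked genes such as Xist and Ddx3y, so those splits say nothing on chance for the other genes. So few splits, without correction over the comparisons, make chance less likely for the counts before that one but do not exclude it. The count of 16 between wild types at 6 months also fell to 0 without Q20-housed female 1. In Q140 against Q20 at 6 months 2 of 45 splits reached 28 and the highest other called 718, many times the real count, which points to a structure of the samples. Chance cannot be excluded by count for Q20 (6 of 45, highest other 2515) and Q50 (4 of 45, highest other 36) against own wild types at 6 months and for Q50 at 10 months (3 of 45, real 9, highest other 88), and those splits point to a structure of the samples too. The counts of 0 for the difference between ages and between sexes at 6 months were reached by 21 of 21 and 45 of 45 splits (highest other 1 and 0), as a count of 0 must be.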
